A study of Mus musculus with 2 samples.

How the data were processed

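Single cells of embryonic mouse hearts were measured in 2 pooled droplet libraries of the 10x Chromium 3' chemistry. Before pooling, the cells of each sample were stained with their own MULTI-seq barcode, a lipid-anchored DNA oligonucleotide that marks the sample a cell came from. The deposited barcode key names 8 barcoded samples, 4 in each pool, with 1 control and 1 ablated sample of each of 2 stages per pool. The labels do not say whether a barcoded sample was a single heart, so they are called barcoded samples here.

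The submitters' processing notes name Cell Ranger 7.1.0 and the mouse build GRCm38. The gene annotation, the filters on cells and the clustering settings were not given in the sources used here. Per the file headers, the deposited tables give for each cell the UMI count and the count of genes with at least 1 UMI, both raw whole numbers. The deposited percent of mitochondrial UMIs is relative to all UMIs of the cell. The deposited S score and G2M score, with the phase called for each cell, are the authors' per-cell cell cycle values. Every cell of the 2 tables of single pools was called single by the authors, so cells with several barcodes or with none were not analysed here, and the planned description of the barcode assignment could not be made. No doublet caller was run, because no gene values were used here. For the same reason UMIs could not be thinned to an equal depth, and no gene is named.

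The 2 tables of single pools held 13246 cells, 7251 of pool 1 and 5995 of pool 2, with cluster numbers made within each pool. The lowest UMI count of a cell was 501, the lowest number of genes was 321 and the highest mitochondrial percent was 39.9. Names of cell types and the numbers of clusters made over both pools came from the authors' integrated table. The copy used here ended inside a row and held 4546 cells, all of pool 1 and 62.7% of that pool, in the order of the cell barcodes; the rest of that table was not analysed here. Among pool 1 cells with and without a name, the makeup over the 15 clusters of the pool did not differ detectably (chi-square test on cells, 13.4 on 14 degrees of freedom, p = 0.495), which compares 2 parts of the same library. Within single barcoded samples the p of this chi-square test lay between 0.0972 and 0.924.

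Cell type shares therefore had 1 barcoded sample per stage and condition. Within a stage they had no test. Over both stages the planned exact permutation test, with labels permuted within stage, had 4 reassignments and could give no p below 0.5. Shares were given with exact (Clopper-Pearson) binomial intervals at 95%, and differences of shares with limits combined from those intervals by the square-and-add method. Intervals and the limit for a count of 0, set at 3 cells over all cells of the sample, cover counting error only and not the spread between hearts. In binomial draws with the fibroblast shares of the E16.5 samples of pool 1, the exact interval held the true control share in 94.3% of 1000 draws. The interval of the ablated minus control difference held the true value in 95.2%. Intervals at E18.5 and those of small cluster shares were not checked, and the draws held no spread between hearts.

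UMI counts, detected genes and mitochondrial percent were summarised as the median per barcoded sample and compared over all 8 samples with two-sided exact permutation tests. Within a stage, 6 reassignments of 2 against 2 samples were possible. Over both stages, labels were permuted within stage and pool, since the key says which samples shared a pool, which gave 16 reassignments. Adjusted p-values are by the Benjamini-Hochberg method over 4 measures. The fourth, the share of cells above 5% mitochondrial UMIs, was added after the medians were seen. None of these permutation tests could reach 0.05: the smallest p possible was 0.333 within a stage and 0.125 over both. No test that assumes a distribution of the values was run. Nothing in the labels says that samples of a group came from separate animals. Within a stage these p-values therefore measure the spread between samples, which may be technical. Over both stages they rest on how alike the differences between samples of a shared stage and pool were.

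Items were named by a rule set before the data were examined: fibroblasts, every cell type, and the 5 clusters of each table with the largest absolute log2 ratio of mean shares among clusters of at least 50 cells. Phases were compared for types with at least 20 cells in both samples. Alternatives were another denominator, a log2 scale with 0.1 percentage points added, a centred log ratio with 0.5 cells added, removal of the 10% of cells with the lowest or highest UMI count or the highest mitochondrial percent of each pool, each pool alone, samples left out in turn, and a minimum of 50 cells. Chosen after seeing the data were the non-cardiomyocyte denominator, the weighting of names to all cells of pool 1 through its own clusters, the groups of fibroblast clusters, and the other blocking of the permutation tests. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.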

Results

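The series set out to compare hearts with and without genetic ablation of fibroblasts at 2 stages of mouse development, E16.5 and E18.5. In ablated samples, a Pdgfra-CreER allele (an inducible recombinase expressed where the fibroblast gene Pdgfra is active) was combined with Rosa-DTA, which makes the toxic diphtheria toxin fragment A in cells that recombine. Control samples carried Rosa-DTA without the recombinase. In pool 1, 3914 cells came from the E16.5 control, 1070 from the E16.5 ablated, 923 from the E18.5 control and 1344 from the E18.5 ablated sample. In pool 2 the numbers were 975, 2734, 762 and 1524 in the same order. The total UMI count per sample ranged from 9225383 to 49416483. Cell type names were available here for 4 barcoded samples of pool 1, with 2435, 665, 579 and 867 named cells. Shares of cell types had no replicates within a stage, so they were not tested there, and the intervals cover counting error only.

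Fibroblasts made up a smaller share of the cells in the ablated than in the control sample at both stages. At E16.5, 513 of 2435 control cells were fibroblasts, or 21.1% (95% exact interval 19.5 to 22.7), against 84 of 665 ablated cells, or 12.6% (10.2 to 15.4). At E18.5 the shares were 46.1% (42.0 to 50.3) in the control and 30.3% (27.3 to 33.5) in the ablated sample. The differences were -8.44 percentage points (-11.4 to -5.24) at E16.5 and -15.8 points (-20.9 to -10.6) at E18.5, or 1.67-fold and 1.52-fold lower. Over both stages the mean difference was -12.1 points (exact permutation test within stage, 2 samples per condition, p = 0.5, adjusted p = 0.8, lower in 2 of 2 stages), and 0.5 is the smallest p that test can give here. Fibroblasts remained in both ablated samples. Among non-cardiomyocyte cells, a denominator added after seeing the data, the fibroblast share was 41.7% against 30.3% at E16.5 and 54.4% against 41.8% at E18.5.

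**Figure D1:**
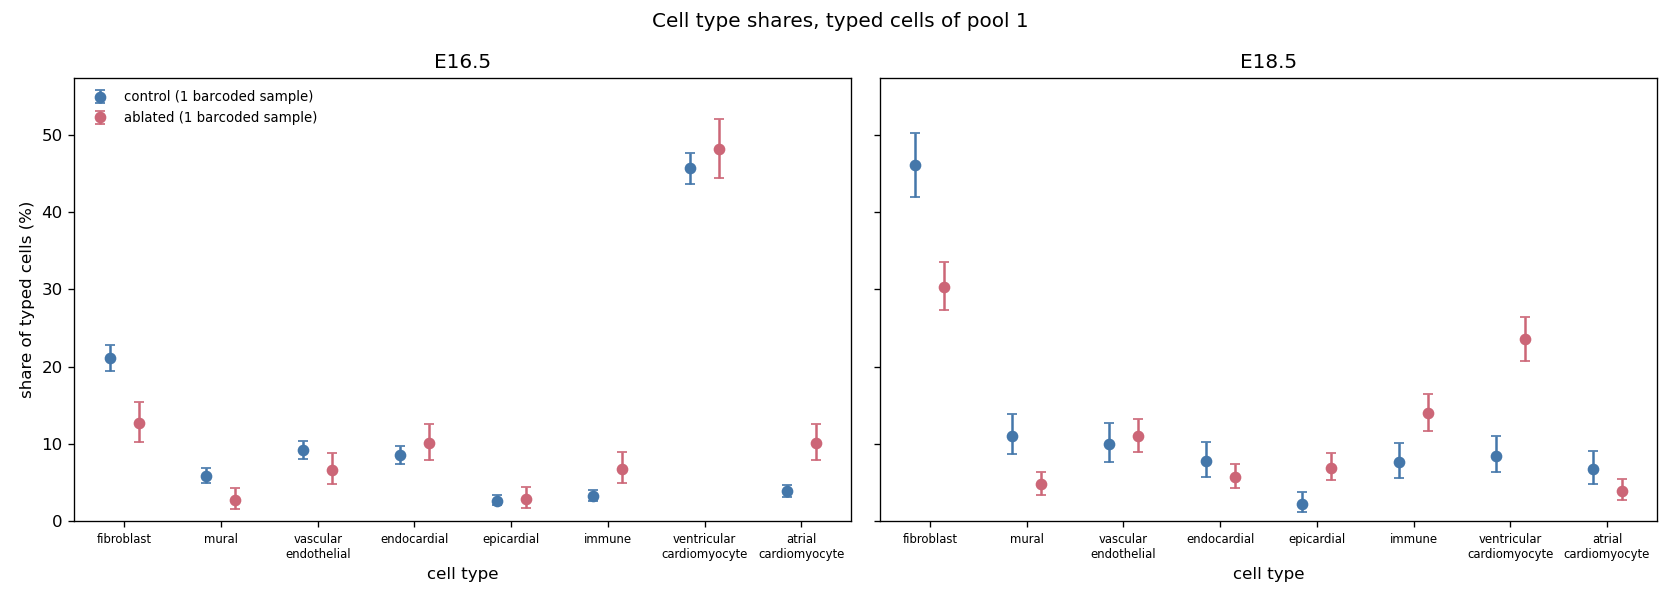
Share of named cells (%, vertical axis) for 8 cell types in the control and ablated barcoded samples of pool 1 at E16.5 and E18.5. Points are single samples and bars are 95% exact binomial intervals; fibroblasts stood at 21.1% against 12.6% at E16.5 and at 46.1% against 30.3% at E18.5.

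Mural cells, the pericytes and smooth muscle cells around vessels, were also a smaller share in both ablated samples. Their share was 5.83% in the control and 2.71% in the ablated sample at E16.5, a difference of -3.12 points (-4.61 to -1.34), and 11.1% against 4.73% at E18.5, a difference of -6.32 points (-9.46 to -3.39). Of the 265 mural cells, 88 lay in the mainly fibroblast cluster 1 of pool 1, which held -1.04 of the -3.12 points at E16.5 and -5.01 of the -6.32 points at E18.5. Immune cells were a larger share, with 3.24% against 6.77% at E16.5 (difference 3.52 points, 1.57 to 5.81) and 7.60% against 13.96% at E18.5 (6.36 points, 3.02 to 9.56). Ventricular cardiomyocytes made up 45.7% against 48.3% at E16.5, where the interval of the difference held 0 (-1.79 to 6.92), and 8.46% against 23.5% at E18.5, a difference of 15.1 points (11.3 to 18.7). Among non-fibroblast cells the ventricular cardiomyocyte difference at E16.5 was -2.66 points, and among non-cardiomyocyte cells the immune difference was 9.82 points at E16.5 and 10.3 at E18.5. Among non-fibroblast cells the mural difference at E18.5 was -13.7 points. Epicardial cells, of the outer layer of the heart, were 2.63% against 2.86% at E16.5, not distinguishable at this depth (and -0.426 points apart without the 10% of cells with the highest UMI counts), and 2.25% against 6.92% at E18.5 (4.68 points, 2.44 to 6.84).

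Atrial cardiomyocytes were a larger share of the ablated sample at E16.5, 3.82% against 10.1%, and a smaller share at E18.5, 6.74% against 3.92%, a difference of -2.81 points among all cells and -6.87 among non-fibroblast cells. At E16.5 the atrial cluster 21, with a median of 5170.5 UMIs and 18.9% mitochondrial, was 0.903% against 5.41%. Atrial clusters 36 and 22 were 0.411% against 2.71% and 0.739% against 1.35%, and cluster 28 was 1.77% against 0.602%. The E16.5 difference was 5.86 points without the 10% of cells with the lowest UMI counts. Without the 10% with the highest mitochondrial percent it was 5.435. Vascular endothelial cells stood at 9.20% against 6.62% at E16.5 and at 10.0% against 11.0% at E18.5. Endocardial cells, which line the chambers, stood at 8.50% against 10.1% and at 7.77% against 5.65%; among all cells both endocardial differences had intervals that held 0, as did the vascular endothelial difference at E18.5 (-2.45 to 4.19). The endocardial share of non-cardiomyocyte cells at E16.5 was 16.8% (14.8 to 19.1) against 24.2% (19.3 to 29.7), 7.34 points higher, and the endocardial difference among non-fibroblast cells at E18.5 was -6.31 points. Among non-fibroblast cells the vascular endothelial difference at E18.5 was -2.86 points. Both cardiomyocyte types together were 49.5% of control and 58.3% of ablated cells at E16.5, and 15.2% and 27.5% at E18.5.

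Among all named cells, the control samples of the 2 stages differed more than the ablated and control samples of either stage did for fibroblasts and ventricular cardiomyocytes. Fibroblasts were 21.1% at E16.5 and 46.1% at E18.5, a difference of 25.05 points (20.6 to 29.5). Ventricular cardiomyocytes were 45.7% and 8.46%, a difference of -37.2 points (-40.2 to -34.0). Mural cells were 5.22 points higher at E18.5 (2.59 to 8.20), immune cells 4.35 points (2.19 to 6.91) and atrial cardiomyocytes 2.92 points (0.837 to 5.38). Among all cells the intervals of the vascular endothelial, endocardial and epicardial differences held 0. Among non-cardiomyocyte cells the fibroblast difference between stages was 12.6 points, the mural 1.48, the vascular endothelial -6.41, the endocardial -7.68 and the epicardial -2.56 points. For fibroblasts this was close in size to the ablation differences among the same cells, -11.4 points at E16.5 and -12.6 at E18.5. Each stage was a single sample, so stage and sample cannot be separated. Pool 2 had no cell type names. Cells above 5% mitochondrial UMIs, mostly cardiomyocytes among named cells, were 47.5% at E16.5 and 13.7% at E18.5 in the pool 1 controls. In the pool 2 controls they were 25.4% and 19.4%, a smaller difference between stages.

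The ablation difference in the fibroblast share was 7.34 points further below 0 at E18.5 than at E16.5 (difference of differences -7.34). Among non-cardiomyocyte cells it was -1.15. On the log2 scale the same contrast was 0.13, of opposite sign, because the share in the E18.5 control was higher. The difference of differences was 12.5 points for ventricular cardiomyocytes, 4.45 for epicardial, 3.52 for vascular endothelial and 2.83 for immune cells, and -9.07 for atrial cardiomyocytes, -3.69 for endocardial and -3.20 for mural cells. Sizes depended on the denominator. For immune cells the value was 0.458 among non-cardiomyocyte cells and of opposite sign on the log2 scale (-0.17). With 1 sample per stage and condition, exact permutation of the condition within each stage could give no p below 0.5 for this interaction. The signs of the differences at each stage alone fix that p, so it says nothing about their sizes.

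The named cells fell into 40 integrated clusters, each of 1 cell type, of which 9 were fibroblast clusters. By the naming rule, 4 of the 5 named clusters were fibroblast and 1 was mural. Cluster 4 was 6.94% (5.96 to 8.02) of control cells and 2 of 665 ablated cells (0.301%, 0.0364 to 1.082) at E16.5, and 21.4% (18.1 to 24.99) against 0.807% (0.325 to 1.66) at E18.5. Cluster 18 was 4.27% of control cells and 0 of 665 ablated cells at E16.5, and 5.01% against 1.15% at E18.5. At the limit of 3 cells, the E16.5 ablated share was up to 0.451%, or 9.47-fold lower than the control share as measured. The exact interval reached 0.553%, which makes that fold smaller. Cluster 27 was 2.46% against 0.301% at E16.5 and 1.21% (0.487 to 2.48) against 0.231% (0.0279 to 0.831) at E18.5. Cluster 25 had 0 of 2435 and 0 of 579 control cells, and made up 1.05% (0.424 to 2.16) and 5.42% (4.01 to 7.14) of ablated cells. The limit of 3 cells allows control shares of up to 0.123% and 0.518%. Against that limit the ablated shares as measured were 8.54-fold and 10.5-fold higher. The exact intervals of the control shares reached 0.151% and 0.635%, which makes these folds smaller. The mural cluster 11 was 3.53% against 1.96% at E16.5 and 7.77% against 2.31% at E18.5. The genes behind the clusters were not analysed here, so a lower cluster share can be fewer cells or cells placed in another cluster.

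The other fibroblast clusters were chosen for mention after their values were seen. Cluster 3 was not distinguishable at this depth, with 3.61% (2.91 to 4.43) against 2.86% (1.73 to 4.43) at E16.5 and 13.47% (10.8 to 16.5) against 10.5% (8.54 to 12.7) at E18.5; among fibroblasts alone it was 17.2% against 22.6% and 29.2% against 34.6%. Cluster 13 was 1.60% against 4.21% at E16.5 (difference 1.098 to 4.48 points) and 2.25% against 3.92% at E18.5, where the interval held 0. For cluster 19 only the E18.5 difference had an interval above 0 (1.27 to 5.12 points), and for cluster 29 both intervals held 0. Cluster 38, like cluster 25, held 0 control cells, with 3 and 15 ablated cells. Clusters 4, 18 and 27 together were 64.9% of control and 4.76% of ablated fibroblasts at E16.5, and 59.9% and 7.22% at E18.5.

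**Figure D2:**
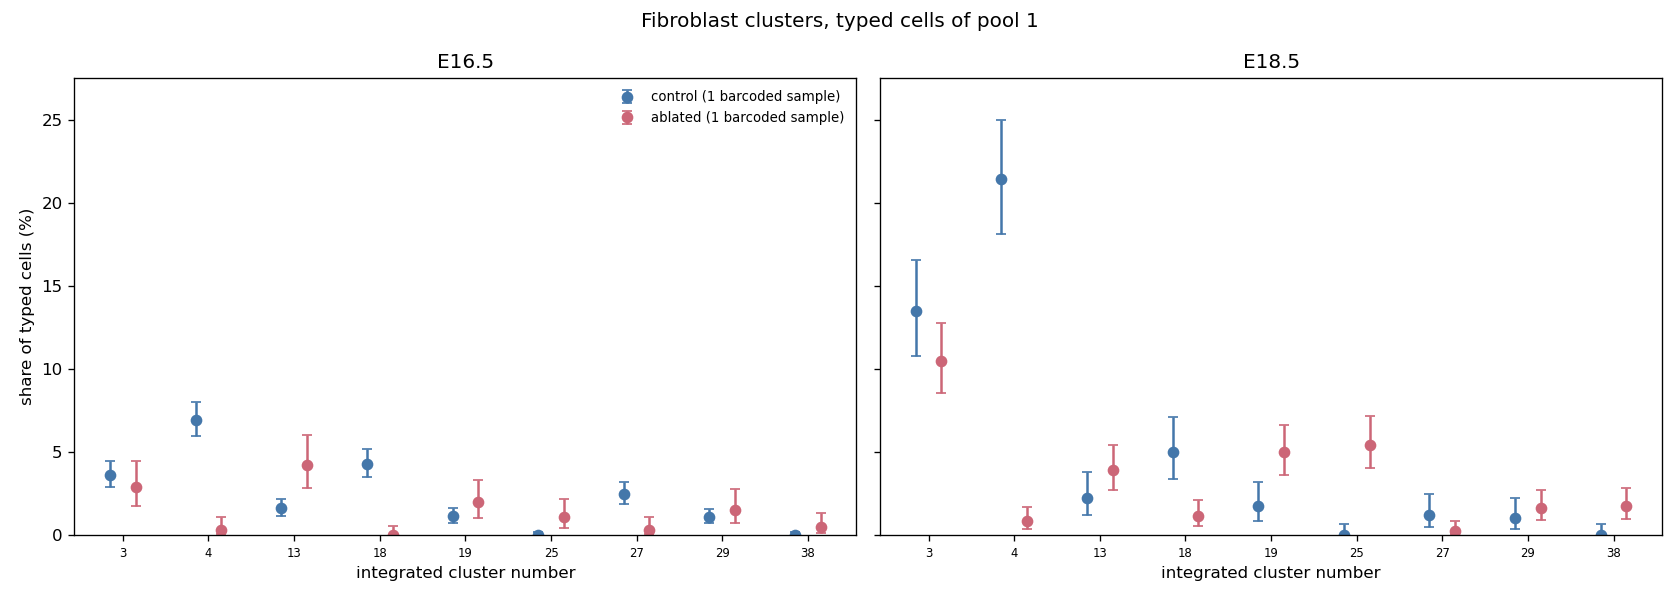
Share of named cells (%, vertical axis) for each of the 9 fibroblast clusters (cluster number, horizontal axis) in the control and ablated barcoded samples of pool 1 at E16.5 and E18.5, with 95% exact binomial intervals. Clusters 4, 18 and 27 lay lower in both ablated samples, and clusters 25 and 38 held ablated cells only.

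The clusters made within each pool covered all cells of the pool. In pool 1, cluster 1, in which 382 of 473 named cells were fibroblasts and 88 were mural, was 11.6% against 1.78% at E16.5 and 28.7% against 2.23% at E18.5. Cluster 12, with 146 fibroblasts among 151 named cells, was 4.29% against 0.561% and 4.98% against 1.04%. Cluster 14, with 131 fibroblasts among 133, was 1.61% against 4.39% and 2.17% against 6.40%. The mainly mural cluster 8 was 4.50% against 1.68% and 6.501% against 3.79%, and the mainly epicardial cluster 11 was 2.78% against 3.08% and 2.60% against 7.96%. Pool 2 had cluster numbers without cell type names. There, cluster 8 was 13.03% (11.0 to 15.3) against 1.17% (0.802 to 1.65) at E16.5 and 16.4% (13.8 to 19.2) against 3.15% (2.33 to 4.15) at E18.5. Cluster 13 was 2.15% against 1.17% and 3.41% against 1.57%. Cluster 0, whose median mitochondrial percent was 7.41, was 7.69% against 20.4% and 5.25% against 25.5%. Cluster 4, with a median of 6.54, was 7.49% against 8.78% and 3.15% against 11.8%. Cluster 2 was 8.41% against 8.92% and 18.6% against 5.58%.

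More fibroblasts were called in S or G2M phase in the ablated samples; over all fibroblasts the intervals of both differences came close to 0. The share was 47.8% (43.4 to 52.2) in the control and 60.7% (49.5 to 71.2) in the ablated sample at E16.5, a difference of 12.96 points (0.856 to 24.3), and 30.3% against 38.8% at E18.5, a difference of 8.45 points (0.0875 to 16.7). The fibroblasts compared came from different clusters, with clusters 4, 18 and 27 holding most of them in the controls and clusters 3, 13, 19 and 29 in the ablated samples. Among fibroblasts of clusters 3, 13, 19 and 29, a group made after seeing the data, the share was 39.4% (32.3 to 47.0) against 62.9% (50.5 to 74.1) at E16.5, a difference of 23.4 points, and 28.97% (20.6 to 38.5) against 36.8% (29.8 to 44.3) at E18.5, or 7.84 points. Cluster mix is not removed within this group. At E16.5, cluster 13 made up 39 of its 180 control cells and 28 of its 70 ablated cells. In clusters 4, 18 and 27 the share called in S or G2M was 52.3% against 2 of 4 ablated cells at E16.5, and 31.3% (24.2 to 39.0) against 16 of 19 ablated cells (60.4 to 96.6%) at E18.5, both below the minimum of 20 cells. Cluster mix is not removed here either. At E18.5, cluster 18 made up 29 of the 160 control cells and 10 of the 19 ablated cells, so a rise within clusters cannot be read from these shares. Median G2M scores of fibroblasts were -0.158 and -0.0496 at E16.5 and -0.189 and -0.180 at E18.5. Median S scores were -0.0441 and -0.0571 at E16.5, and -0.0901 and -0.0857 at E18.5. Ventricular cardiomyocytes stood at 44.9% against 40.5% and at 32.7% against 29.9%, and vascular endothelial cells at 63.4% against 63.6% and at 39.7% against 44.2%. Endocardial cells stood at 24.6% against 20.9% and at 28.9% against 24.5%. Atrial cardiomyocytes stood at 35.5% against 50.7% and at 33.3% against 8.82%, and immune cells at 36.7% against 35.6% and at 20.5% against 21.5%. Mural cells stood at 28.1% against 34.1% at E18.5, where both samples had enough cells. Cycling itself is not read from these calls, since depth could not be equalised and RNA from outside the cells stays open. The median UMI count of fibroblasts at E16.5 was 11776 in the control and 9538.5 in the ablated sample, and at E18.5 it was 9264 and 9515. Among fibroblasts with at least 9910 UMIs, their overall median and a cut made after seeing the data, both intervals held 0. Their differences in S or G2M calls were 7.03 points (-10.3 to 21.9) at E16.5 and -1.98 points (-15.1 to 11.2) at E18.5.

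Mitochondrial percent was higher in the ablated than the control sample in 4 of 4 pairs that shared a stage and a pool. The sample median was 2.55% ± 1.39 (SD, n = 4) in controls and 3.67% ± 1.42 in ablated samples, a difference of 1.12 points (exact permutation test, p = 0.125, adjusted p = 0.25), which is the smallest p this permutation test can give. The share of cells above 5% mitochondrial UMIs was 26.5% ± 14.8 in controls and 39.6% ± 11.1 in ablated samples (n = 4), also higher in 4 of 4 pairs (exact permutation p = 0.125, adjusted p = 0.25). These SDs span both stages and both pools, so they are not the spread of replicates, and the test compared samples within pairs. It was 47.5% against 52.6% and 25.4% against 36.9% at E16.5 in pools 1 and 2, and 13.7% against 26.1% and 19.4% against 42.7% at E18.5. Without the E16.5 control of pool 2, the E16.5 difference of this share turned from 8.30 to -2.73 points, and that over both stages went from 13.1 to 7.57. That sets the E16.5 ablated samples of both pools against the control of pool 1 alone, so the difference between pools enters. Within pools 1 and 2 the E16.5 differences of this share were 5.12 and 11.5 points. Without the E18.5 ablated sample of pool 2, the E18.5 difference went from 17.9 to 9.58 points, and that of the median mitochondrial percent from 1.18 to 0.169. The median difference over both stages was lowest, at 0.490, without the E16.5 control of pool 2. In named cells, 85.4% of ventricular and 65.7% of atrial cardiomyocytes lay above 5%, against 3.21% to 11.6% of the other types.

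**Figure D3:**
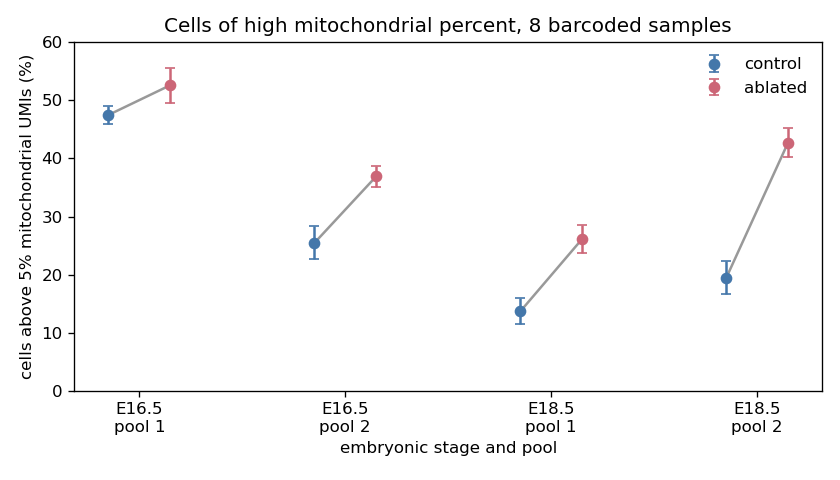
Share of cells above 5% mitochondrial UMIs (%, vertical axis) in the 8 barcoded samples, with lines joining the control and ablated sample of the same stage and pool and bars for 95% exact binomial intervals. The ablated sample was higher in 4 of 4 pairs.

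UMI counts and detected genes did not differ in one direction over the pairs that shared a stage and a pool. The ablated sample was higher in 3 of 4 pairs for UMI counts and in 2 of 4 for genes. The SDs given here span both stages and both pools. The median UMI count was 9796 ± 691 (SD, n = 4) in controls and 10162 ± 1604 in ablated samples (exact permutation p = 0.625, adjusted p = 0.833), and the median number of genes was 3411 ± 124 and 3396 ± 257 (exact permutation p = 0.875, adjusted p = 0.875).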

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

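The differences between stages given here were not tested with any power: exact permutation of the condition within stage gave p = 0.5 for each, the smallest it can give. No explanation was tested for them.

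The ablated and control samples of pool 1 differed in opposite directions at the 2 stages for several items, each with 1 sample per stage and condition. For the atrial cardiomyocyte share, the difference was 6.26 points at E16.5 and -2.81 at E18.5, a difference between stages of -9.07 points. The atrial cells also differed in quality at E16.5, with median UMI counts of 10751 in the control and 6551 in the ablated sample. Their median mitochondrial percents were 5.83 and 14.6. The vascular endothelial share gave -2.58 and 0.940, 3.52 points apart, and the endocardial share 1.57 and -2.12, or -3.69 points, both endocardial intervals holding 0. The vascular endothelial difference at E18.5 was not above 0 among non-fibroblast cells (-4.08 and -2.86 points at the 2 stages) or without the 10% of cells with the lowest UMI counts (-0.0229 points at E18.5), so its opposite direction depended on these choices. Atrial cardiomyocytes called in S or G2M phase gave 15.3 and -24.5 points, or -39.8 points; at E18.5 this rested on 3 of 34 ablated cells. Immune cells called in these phases gave -1.15 and 1.03 points, or 2.19 points, both within counting error (36.7%, interval 26.1 to 48.3, against 35.6%, 21.9 to 51.2, and 20.5%, 9.80 to 35.3, against 21.5%, 14.5 to 29.9). In pool 2, the share of cluster 2 gave 0.514 (within counting error) and -13.1 points, or -13.6 points; without the 10% of cells with the highest UMI counts the first was -0.0585, so both were then below 0.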

How the results depend on the processing

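The denominators added after seeing the data, the weighting and the other blocking were not planned. Of 441 alternative values for 94 results, 380 stayed within the counting interval of the main value, kept its sign on another scale or, for tested results, kept direction and side of the threshold. Of these 380, 7 changed sign within the interval. A further 41 moved beyond it, 8 of them with a change of sign, and 20 reversed, so 35 had the opposite sign in all. The fibroblast share was lower in both ablated samples under every alternative run. All 33 values weighted to all cells of pool 1, and all 39 without the 10% of cells with the lowest UMI counts, stayed within the counting interval, although the endocardial difference between control stages turned to 1.198 and the vascular endothelial difference at E18.5 to -0.0229. No permutation test reached 0.05 under any alternative, which these permutations cannot do, so this says nothing about stability. Where a value changed, the change of denominator or scale is its construction; otherwise the cause was not tested.

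With non-cardiomyocyte cells as denominator, the ablated minus control difference at E16.5 was -11.4 points for fibroblasts, -5.06 for mural, 7.34 for endocardial and 9.82 for immune cells; at E18.5 it was 6.89 for epicardial and 10.3 for immune cells. The difference between control stages was then 12.6 points for fibroblasts, 1.48 for mural, -6.41 for vascular endothelial, -7.68 for endocardial and -2.56 for epicardial cells, and the difference of differences was -1.15 for fibroblasts and -8.72 for endocardial cells. Clusters 4, 18 and 27 together gave -25.7 and -29.6 points at the 2 stages, clusters 3, 13, 19 and 29 gave 10.6 and 7.14, and clusters 25 and 38 gave 3.61 and 9.86.

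With non-fibroblast cells as denominator, the difference was -2.66 points for ventricular cardiomyocytes at E16.5, and at E18.5 -13.7 for mural, -2.86 for vascular endothelial and -6.31 for endocardial cells and -6.87 for atrial cardiomyocytes. Between control stages it was 13.1 for mural, 6.94 for vascular endothelial, 3.65 for endocardial and 9.99 for immune cells, -42.2 for ventricular and 7.66 for atrial cardiomyocytes. The difference of differences was -9.43 for mural cells, 20.7 for ventricular and -13.6 for atrial cardiomyocytes.

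On the log2 scale the fibroblast difference of differences was 0.13 and as a centred log ratio 0.0901, both opposite in sign to the points scale; for immune cells these were -0.17 and -0.24. The centred log ratio gave -0.0051 for ventricular cardiomyocytes at E16.5 and -0.0600 for vascular endothelial cells between control stages. Without the 10% of cells with the highest mitochondrial percent, ventricular cardiomyocytes differed by -31.7 points between control stages, and clusters 4, 18 and 27 by -14.8 points at E16.5.

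The median UMI difference was 784 at E16.5 in pool 2 alone and -663.25 over both stages in pool 1 alone, and the mean log10 UMI count differed by 0.00111 at E16.5. The difference in median genes was 76 at E16.5 and 116.5 over both stages in pool 2 alone, and -15 at E18.5 in pool 1 alone. Leaving out 1 sample breaks its pairing with the other condition in its pool, so differences between pools enter the ranges that follow. Leaving out each sample in turn, the UMI difference ranged from -1151.5 to 476.5 at E16.5, from -586.25 to 2728 at E18.5 and from -461.9 to 1195 over both stages. The gene difference ranged from -249.5 to 47.5, from -161.75 to 303.75 and from -131.4 to 101.4. The difference in median mitochondrial percent ranged from -0.202 to 2.31 points at E16.5, and that in cells above 5% from -2.73 to 19.3 points; at E18.5 they ranged from 0.169 to 2.197 and from 9.58 to 26.2, and over both stages from 0.490 to 1.75 and from 7.57 to 18.6.

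For cell type shares, phases and clusters no paired analysis by pool was possible because each set of names or cluster numbers covered 1 pool, so the groups shared 1 replicate number. With the stage as block, the exact permutation p was 0.5 or 1, and 0.5 for the fibroblast share under every alternative. Each pool alone, summed weighting, and leaving out samples could not be run for them, with names from 1 sample per stage and condition. A minimum of 200 cells per sample removed none. For the tested measures, the replicate block within a stage, and no replicate block over both stages (exact permutation p = 0.222 for median mitochondrial percent and 0.167 for cells above 5%, smallest possible 0.0556), changed no call.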

Other observations

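All tests in this part were chosen after the results were seen. Clusters 25 and 38, which held ablated cells only, had low median mitochondrial percents of 0.617 and 0.739, against 1.40 in cluster 4 and 1.62 in cluster 3. Their median UMI counts were 12326 and 13214.5. Among fibroblast clusters such low medians were particular to them, since the others had medians from 1.40 (cluster 4) to 4.59 (cluster 27). Outside fibroblasts, low medians also occurred in immune clusters of lower depth. Immune cluster 35, with 5 cells, all ablated, had 0.560 at a median of 1055 UMIs. Immune cluster 37, with 21 of 29 cells from the E18.5 ablated sample, had 0.620 at a median of 3766 UMIs. Most of cluster 25, 45 of 54 cells, lay in cluster 2 of pool 1, beside 272 cells of cluster 3.

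Fibroblast clusters 4, 18 and 27 had low shares in both ablated samples of pool 1. A higher recovery of cardiomyocytes would leave their share among non-cardiomyocyte cells equal, yet the ablated share there was 0.0927 of the control share or less at both stages. Among cells at or above the median UMI count of 9690 the ratio was 0.0788 or less, which argues against shallow cells. In points of share among non-cardiomyocyte cells, gains of the other fibroblast clusters equalled at most 57.5% of the loss. Part of such gains can be arithmetic, since losing cells of some clusters raises every other share. The 57.5% therefore does not measure cells that changed cluster. The total fibroblast share of non-cardiomyocyte cells was lower within each stage (-11.4 points, -17.5 to -5.00, and -12.6, -18.5 to -6.55), which goes against a change of cluster as the whole account. These intervals cover counting error only, and the total was 1.38-fold and 1.30-fold lower, with no replicates to give its spread. In cells above 5% mitochondrial UMIs, a share measured in all samples, the E16.5 controls of the 2 pools were 1.87-fold apart, pool effect included. The ablated to control ratio of that share differed between pools only 1.31-fold at E16.5 and 1.15-fold at E18.5. Among named cells, most cells above 5% were cardiomyocytes, which the non-cardiomyocyte denominator leaves out. Neither value therefore gives the spread of the fibroblast share. Whether all of the loss may be a change of cluster stays open for lack of replicates. Loss of these cells through the ablation is a hypothesis that 1 sample per stage and condition, without gene values, could not test.

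Cells above 5% mitochondrial UMIs were more frequent in the ablated samples of pool 1. Higher mitochondrial percent in every cell type is argued against: in named cells, the median ablated to control ratio over the 6 non-cardiomyocyte types was at most 0.996. The ratio of the sample medians, over all cells of each sample, was 1.16 and 1.18. Single types went both ways, with ratios up to 1.30 (mural) and 1.096 (vascular endothelial) at E18.5 and 1.08 and 1.02 for fibroblasts. At E16.5 the medians rose in ventricular (10.2% to 11.7%) and atrial cardiomyocytes (5.83% to 14.6%). At E18.5 both fell (9.996% to 7.88% and 7.17% to 5.25%), so a rise within cardiomyocytes stays open at E16.5. In named cells, the share above 5% was 46.9% against 53.5% at E16.5 and 15.7% against 26.2% at E18.5. The mix of cell types alone gave 72.8% of that difference at E16.5 and 99.6% at E18.5. This was short at E16.5 of the level of 80% set for both stages, so a larger share of cardiomyocytes may account for most of the difference. Loss of fibroblasts alone would leave the cardiomyocyte share of non-fibroblast cells equal; that share was 11.2 points higher at E18.5 (4.57 to 17.6) and 4.03 points higher at E16.5, where the interval held 0. The share was 1.06-fold and 1.40-fold higher, below 1.87-fold but at E18.5 above 1.15-fold. The 1.87-fold and 1.15-fold come from cells above 5% mitochondrial UMIs and not from the cardiomyocyte share, which has no replicates. Whether loss of fibroblasts alone was enough also stays open. Recovery of cardiomyocytes during dissociation and a biological difference stay open, as do the samples of pool 2.

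The higher share of fibroblasts called in S or G2M phase was not separated from its technical explanations. The mix of fibroblast clusters alone gave 5.25 of 14.4 points at E16.5 and 5.42 of 10.96 at E18.5, the differences with clusters 25 and 38 left out. At E16.5 the control side still held cluster 18, which had 104 control and 0 ablated cells. Besides, 3 of the clusters consisted of 1 class of phase, so clusters and phases are not independent and this split decides nothing. Among fibroblasts at or above their median UMI count of 9910, the difference was 7.03 points (-10.3 to 21.9) at E16.5 and -1.98 points (-15.1 to 11.2) at E18.5, too wide to exclude depth as a possible explanation.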
